A study of Homo sapiens with 6 samples.

How the data were processed

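MicroRNAs were profiled in 6 samples of human foot skin epidermis, 3 DFS and 3 NFS. Per the labels' protocols, the epidermis was collected by laser capture from formalin-fixed tissue, total RNA was extracted with an FFPE kit, and cDNA was amplified with SYBR Green on ready-made microRNA PCR panels. The deposited non-normalized table gives 1 Ct per well in PCR cycles, with a blank where no Ct was given. The software and threshold that set the Ct are not given in the sources used here, and the values stop at 40.

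Per the labels, the authors normalized the Ct to SNORD49 with the GenEx software. The deposited normalized table is on a log2 scale and holds 200 assays, 196 human microRNAs and 4 controls. Compared with the non-normalized table, 996 of its 1200 values equal the SNORD49A Ct minus the assay's Ct (tolerance 0.001). A further 182 values are lower by a constant of 0.984 cycles, in 32 assays, 31 of them on the second panel. The remaining 22 values equal 1 replacement Ct of 37.492, and 18 of them are in DFS. They stand for Cts of 35.51 or later, counted with the constant added where it applies. The constant cancels in a comparison of groups, while a replaced value sets the size of a difference. How the 200 assays were chosen is not given in the sources used here. Only 2 column names of the normalized table match a sample title, so the other columns were used by their group alone, and its samples are called DFS A to C and NFS A to C. The deposited fold change table holds, per the file headers, the log2 difference of the authors' group means, a signed fold change, a p-value and adjusted p-values, with the test not named. Its p equals that of an ordinary 2-sample linear model for 195 of 195 assays with a numeric p (tolerance 1e-04).

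The 196 human assays of the normalized table were compared between DFS and NFS with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group only, 2-sided) and Benjamini-Hochberg adjustment over all assays, at an adjusted p of 0.05. eBayes estimated an infinite prior, so that all assays shared 1 SD. Values are mean ± SD over samples, and differences are DFS minus NFS with limma's SE. Single values were compared by 2-sided exact permutation tests, whose smallest p here is 0.1. The number of assays with a Ct was counted in the non-normalized table, and fits on that table treated a Ct of 40 as missing.

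Before the data were examined, 18 microRNA lists were fixed for keratinocytes, wound healing, inflammation, vessels, other cell types of skin and microRNA families, and the 15 with at least 3 measured members were tested with camera against the other assays (preset correlation 0.01, Benjamini-Hochberg over lists), with an estimated correlation and the rotation test fry beside it. Of these tests, 2 passed with the preset correlation and 0 with an estimated correlation or fry. Lists share members, such as miR-31-5p in the keratinocyte and wound healing lists. The microRNAs named were those past the threshold, those with the largest differences among assays whose groups did not overlap, a fixed set of skin and wound microRNAs with the reference RNAs, the members with the largest differences in each list, assays detected in 1 group alone, and the lowest p-values in each direction of the authors' deposited table.

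Alternatives covered the normalization, the limit on the Ct, the detection filter, missing values, the model of the spread, sample weights, the replicate number as a block, the set test and leaving out each sample in turn. The steps were tested on simulated data for DFS against NFS, with 20 of the 196 assays changed in 50 simulations. The limma fit recovered 0.3% of changes of 1 on the log2 scale, 38.6% of changes of 2 and 96.4% of changes of 4, with 0.06, 0.54 and 1.18 false calls per simulation. A shift of -1 in the 13 measured mesenchymal markers was called in 100% of simulations with the preset correlation and in 20% with an estimated one. The simulated assays were drawn independently, whereas the measured members of this list had an estimated correlation of 0.749. These shares therefore do not show how often camera makes false calls with correlated members. The number of samples, the late Cts and the replaced values limit the precision. Assay names were matched to gene symbols through a RefSeq gene table (GRCh38.p14) for 196 of 196 assays, 174 of them to 1 gene, and no coordinates are given since the files name no genome build.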

Results

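MicroRNAs, the short RNAs that repress target messages, were measured by quantitative PCR in epidermis cut by laser capture from fixed, embedded foot skin. The 6 samples formed 2 groups, 3 of diabetic foot skin without ulcer or neuropathy (DFS) and 3 of non-diabetic foot skin (NFS). Each sample was run in 768 wells that held 752 human assays, and the PCR cycle at which an assay crossed its threshold (Ct) is later where less RNA was present. Between 439 and 521 human assays gave a Ct in a sample. The comparison asked which microRNAs of the epidermis differed between diabetic and non-diabetic skin. Levels are given as the Ct of the small nucleolar RNA SNORD49A minus the Ct of the assay, so that 1 unit is a 2-fold change if each cycle doubles the product and a higher value means more RNA. The labels describe the samples as separate samples of each group and say no more of the donors, so any spread measured is that between these samples. The main limma fit shared 1 SD over all assays, so its p-values do not measure each assay's own spread.

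In the fit with 1 SD shared by all assays, both arms of the miR-31 hairpin were called higher in diabetic epidermis and miR-338-3p lower. The guide arm miR-31-5p, which is known to promote keratinocyte growth and migration at wound edges, lay at -4.78 ± 1.32 in DFS and -8.56 ± 1.81 in NFS (log2, SD, n = 3 each), a 13.7-fold difference (log2 difference 3.77 ± 0.66 SE, limma adjusted p = 1.77e-06). With 1 sample left out the fold ran from 8.73 (without DFS A) to 28.1 (without NFS B). Its partner arm miR-31-3p lay at -7.24 ± 1.20 in DFS and -11.18 ± 2.10 in NFS (SD, n = 3 each), a log2 difference of 3.94 ± 0.66 SE (limma adjusted p = 8.57e-07), and 1 of its NFS values is the authors' replacement for a late Ct. Its fold of 15.3 ran from 7.59 without NFS C, which holds the replacement, to 32.5 without NFS B. miR-338-3p, known from the nervous system, lay at -11.61 ± 1.14 in DFS against -9.12 ± 0.95 in NFS (SD, n = 3 each), and fell by 2.48 on the log2 scale (limma adjusted p = 0.0126), with 1 replaced value in DFS. For these 3 microRNAs every DFS sample lay on one side of every NFS sample, and the exact permutation test gave p = 0.1, the smallest that 3 samples against 3 allow.

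**Figure D1:**
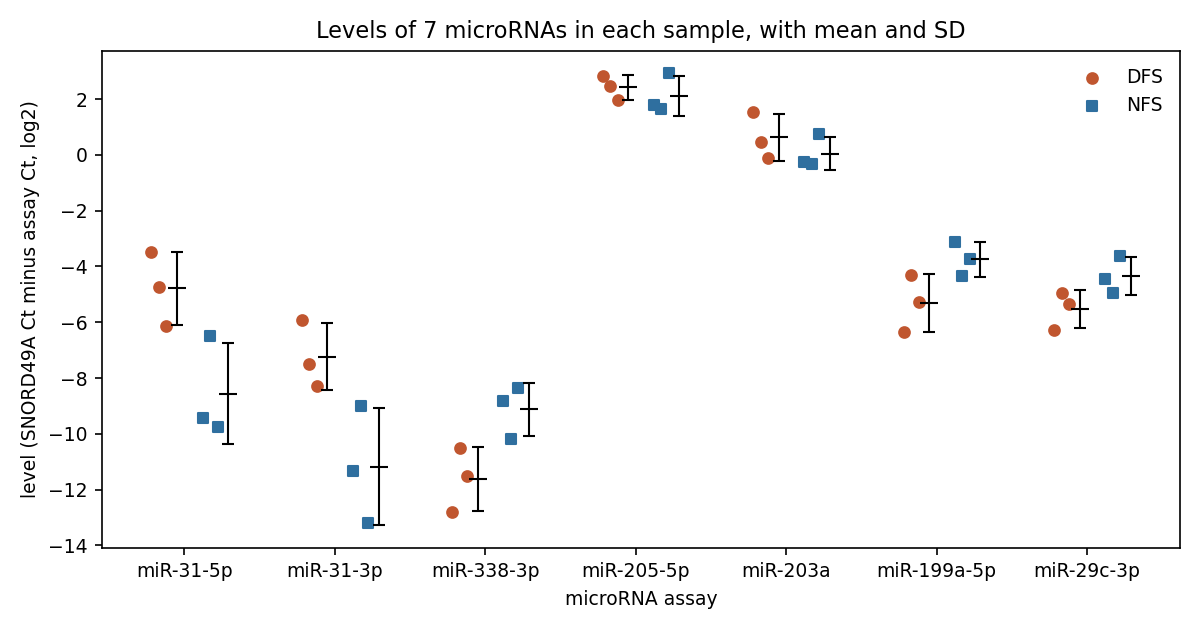
Levels of 7 microRNAs (vertical axis, SNORD49A Ct minus assay Ct, log2) in the 3 DFS samples (circles) and 3 NFS samples (squares), each group with its mean and SD. The groups lie apart for miR-31-5p, miR-31-3p, miR-338-3p and miR-29c-3p and overlap for miR-205-5p, miR-203a and miR-199a-5p, and miR-31-5p averages -4.78 in DFS and -8.56 in NFS.

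These were the 3 of 196 human assays past the adjusted threshold, 2 higher and 1 lower, while 20 had an unadjusted p under 0.05, 3 higher and 17 lower. The limma model gave every assay 1 common SD of 0.812, whereas the SDs of miR-31-5p, miR-31-3p and miR-338-3p themselves were 1.58, 1.71 and 1.05. With each assay's own SD in an ordinary linear model none passed (lowest adjusted p = 0.866, 5 at an unadjusted p under 0.05), and none passed in limma after global mean normalization (lowest adjusted p = 0.267, 25 at an unadjusted p under 0.05, 12 higher and 13 lower), global median normalization (22 unadjusted), quantile normalization (26 unadjusted), without normalization (61 unadjusted) or with missing values filled in (31 unadjusted). The differences themselves stayed large: after global mean normalization that of miR-31-5p was 4.06 ± 1.09 SE, that of miR-31-3p 3.88 ± 1.04 SE and that of miR-338-3p -2.14 ± 0.463 SE. The prior of limma was finite there (4.18 degrees of freedom), so the assays no longer shared 1 SD. The samples of the normalized table are called DFS A to C and NFS A to C here: the call of miR-338-3p was lost without DFS A (adjusted p = 0.288), DFS C (0.0899), NFS A (0.269) or NFS C (0.219), and 11 assays passed without DFS B. It was also lost with the replaced values missing, an alternative chosen after seeing the data (log2 difference -1.89, adjusted p = 0.242), with Ct above 37 missing (adjusted p = 0.304), against the mean of the reference small RNAs (adjusted p = 0.980) and with the trend and robust options of limma (adjusted p = 0.192).

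Across the 196 assays the median log2 difference was -0.32, with 144 assays lower and 52 higher in DFS. The median level per sample was -7.52 ± 0.38 in DFS and -7.34 ± 0.54 in NFS (SD, n = 3 each, exact permutation p = 0.6, 2-sided), so the common shift was within the spread between samples. It was -0.82 without normalization and 0.28 against the mean of the reference small RNAs. With 1 sample left out it ran from -0.63 (without NFS B) to 0.00032 (without NFS C), and list medians are therefore also given relative to the other assays. In 9 assays (4.59%) the groups did not overlap, 3 with DFS above and 6 below, where chance gives 10%. Outside the calls these included miR-136-5p (log2 difference -1.50, limma adjusted p = 0.303), miR-29c-3p (-1.19, adjusted p = 0.650), miR-10b-5p (-0.82, adjusted p = 0.842), let-7f-5p (-0.77, adjusted p = 0.868) and miR-424-5p (-1.90, with 1 replaced DFS value). They also included miR-27a-5p (1.78, adjusted p = 0.243), which was singled out after its values were seen. It has 1 replaced NFS value, and its difference was 1.16 with the measured Ct and 0.567 without that sample.

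Among the keratinocyte microRNAs, miR-31-5p was the 1 member of 15 measured that passed, over all assays and adjusted over the list alone. miR-205-5p, an epithelial microRNA, had the highest level of the 196 assays in all 6 samples, at 2.42 ± 0.44 in DFS and 2.11 ± 0.70 in NFS (SD, n = 3 each). miR-203a, which represses p63 as keratinocytes leave the basal layer, lay at 0.62 ± 0.85 in DFS and 0.05 ± 0.59 in NFS (SD, n = 3 each). Neither difference (0.31 and 0.58) exceeded its limma SE of 0.66. Other members went both ways, with miR-182-5p at 1.10, miR-149-5p at -1.04 and miR-125b-5p at -0.84 on the log2 scale. As a set the list ranked above the other assays (camera, adjusted p = 0.0402 with the preset correlation), though its median difference was -0.01 and its mean 0.23. That call was lost with an estimated correlation (adjusted p = 0.916), without miR-31-5p (adjusted p = 0.453), without DFS A (adjusted p = 0.414), without NFS A (adjusted p = 0.165), and after global mean (adjusted p = 0.0914), global median (adjusted p = 0.0791) or quantile normalization (adjusted p = 0.243) or without normalization (adjusted p = 0.0722). The list's median relative to the other assays was 0.32 in the main setting and 0.377 without NFS A. It was 0.313 after global mean or global median normalization or without normalization, 0.172 without DFS A and 0.155 after quantile normalization. A value subtracted from all assays of a sample cancels in this relative median, so the equal 0.313 in those settings is no separate support.

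The microRNAs listed as fibroblast and mesenchymal markers ranked below the other assays in diabetic epidermis, with all 13 measured members lower in DFS and 11 below the median of all assays. The list's median difference was -0.91, or -0.61 relative to the other assays (camera, adjusted p = 0.0269 with the preset correlation). The call was lost with an estimated correlation (adjusted p = 0.916), without DFS A (adjusted p = 0.414) and without NFS A (adjusted p = 0.165), and no member passed over all assays or adjusted over the list alone. The relative median was -0.48 without DFS A and -0.515 without NFS A. With the preset correlation the call held after global mean (camera adjusted p = 0.00158), global median (0.00163) and quantile normalization (0.00563). With an estimated one it was lost after quantile normalization too (camera adjusted p = 0.877). The members with the largest differences were miR-409-3p (-1.67, with 1 replaced DFS value), miR-199b-5p (-1.65), miR-199a-5p (-1.57) and miR-199a-3p (-1.42), of which the miR-199 family is abundant in fibroblasts. The first rank of miR-409-3p rests on its replaced value. Its difference was -1.49 with the measured Ct and -0.745 without that sample. miR-199a-5p lay at -5.31 ± 1.04 in DFS and -3.74 ± 0.63 in NFS (SD, n = 3 each, limma adjusted p = 0.281). The list's median over its members, relative to each sample's median, was 0.295, 1.08 and 1.38 in DFS and 1.5, 1.55 and 2.39 in NFS, with the lowest value in DFS A, the sample with the most replaced late values (10). In the non-normalized table DFS 1, the same sample by its column name, also stood apart over all assays after global mean normalization. It lay at -11.54 on the first principal component (55.2% of the variance), against -0.63 and -1.70 for the other DFS samples and 1.55 to 6.18 in NFS, and had the fewest assays with a Ct (439). In that table too the list's level was lowest in DFS 1 (0.13 relative to the sample's median, against 0.87 and 1 in the other DFS samples and 1.17 to 2.14 in NFS), so its drop was largest in the sample that stood apart.

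**Figure D2:**
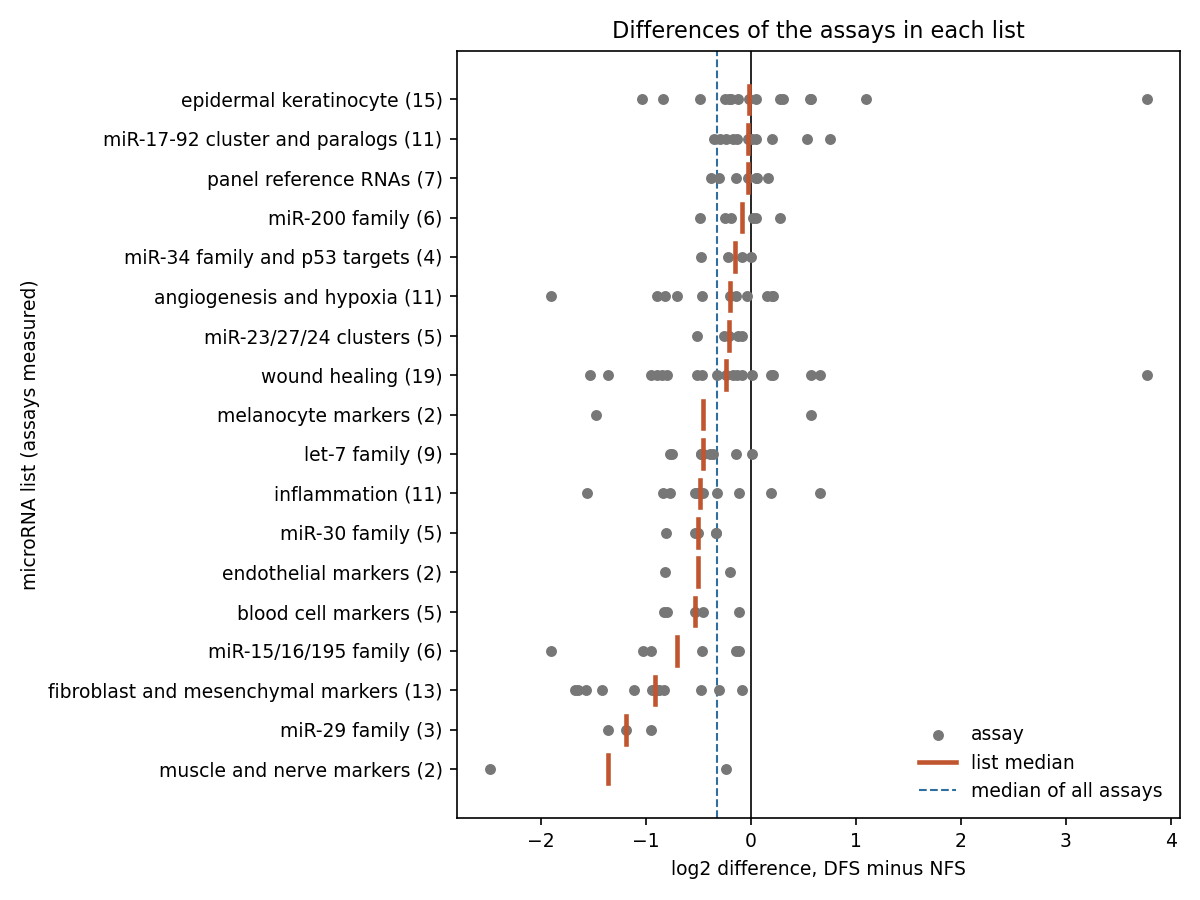
Log2 difference, DFS minus NFS (horizontal axis), of the measured assays (points) in each of 18 microRNA lists (vertical axis, number of assays in brackets), with list medians as upright bars and the median of all 196 assays as a dashed line at -0.32. All 13 fibroblast and mesenchymal markers lie below 0, and miR-31-5p stands apart at 3.77 in the keratinocyte and wound healing lists.

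The miR-29 family, known to repress collagen messages, was lower in DFS in all 3 members. The log2 differences were -1.36 for miR-29b-3p, -1.19 for miR-29c-3p and -0.95 for miR-29a-3p. The family's median was -0.87 relative to the other assays, and it did not pass as a set (camera, adjusted p = 0.260). With the replaced values missing, also chosen after seeing the data, the family did pass with the preset correlation (adjusted p = 0.0492) and did not with an estimated one (adjusted p = 0.985). Of 19 measured wound healing microRNAs miR-31-5p alone passed, over all assays and adjusted over the list alone. The list did not pass (median -0.24, or 0.087 relative to the other assays, camera adjusted p = 0.791). miR-21-5p, which rises in many injured and growing tissues, lay at -1.76 ± 0.76 in DFS and -2.42 ± 0.80 in NFS (SD, n = 3 each), and its difference of 0.66 was no larger than its limma SE of 0.66. miR-100-5p (-1.53), miR-132-3p (0.19) and the hypoxia-induced miR-210 (0.21) did not pass either. The inflammation list had a median of -0.48 over 11 members, or -0.17 relative to the other assays (camera adjusted p = 0.791). Its member miR-146b-5p was at -1.56, with 1 DFS value replaced. It was -0.947 with the measured Ct and -0.598 without that sample. In the same list miR-146a-5p, a brake on NF-kB signalling, was at -0.51 and miR-155-5p at -0.32. In the angiogenesis and hypoxia list (11 measured, median -0.19, mean -0.42, camera adjusted p = 0.791) none passed over all assays, and miR-424-5p fell when adjusted over the list alone (limma adjusted p = 0.047). That call rests on 1 replaced value in DFS A. The difference was -1.31 with the measured Ct (limma adjusted p = 0.323) and -1.09 without DFS A (limma adjusted p = 0.963). It lay at -11.18 ± 1.42 in DFS and -9.28 ± 0.74 in NFS (SD, n = 3 each).

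Markers of other cell types that the capture could hold were mostly lower in DFS, as were 144 of all 196 assays, and miR-338-3p alone passed. Their medians relative to the other assays were -0.21 (blood cell), -0.19 (endothelial), -0.13 (melanocyte) and -1.04 (muscle and nerve). All 5 measured blood cell markers were lower, among them the red cell microRNA miR-451a (-0.83) and the lymphocyte microRNA miR-150-5p (-0.80), with a median of -0.53 (camera adjusted p = 0.791). The endothelial arms miR-126-3p and miR-126-5p differed by -0.19 and -0.82, and of the melanocyte markers miR-204-5p differed by -1.48 and miR-211-5p by 0.57. Of the 2 measured muscle and nerve markers miR-338-3p fell, over all assays and adjusted over the list alone, and miR-128 differed by -0.24. The last 3 lists had too few members for a set test.

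No other list passed in the main setting. The let-7 family was lower in 8 of 9 members (median -0.45, camera adjusted p = 0.791), the miR-30 family in 5 of 5 (median -0.50, adjusted p = 0.791) and the family of miR-15, miR-16 and miR-195 in 6 of 6 (median -0.71, adjusted p = 0.453), where miR-424-5p again fell when adjusted over the list alone (limma adjusted p = 0.0256). It no longer did with its measured Ct (limma adjusted p = 0.176) or without DFS A (limma adjusted p = 0.78). The miR-200 family, which keeps epithelial cells epithelial, had 3 members higher and 3 lower (median -0.09, adjusted p = 0.791), with miR-200c-3p at 0.28 and miR-429 at -0.48. The miR-17 cluster and its paralogs had a median of -0.03 and a mean of 0.03 (11 measured, adjusted p = 0.453), with miR-18b-5p at 0.76 and miR-106b-5p at -0.35, and passed upward after quantile normalization with the preset correlation (adjusted p = 0.03) but not with an estimated one (adjusted p = 0.814). The miR-23/27/24 clusters (5 measured) had a median of -0.21 (adjusted p = 0.811), the miR-34 family and p53 targets (4 measured) -0.15 (adjusted p = 0.794) and the panel's reference microRNAs (7 measured) -0.03 (adjusted p = 0.791). For the miR-200 family, the miR-17 cluster, the miR-34 family, the miR-23/27/24 clusters, the reference microRNAs and wound healing the median was negative while camera ranked the list above the other assays. Medians relative to the other assays were -0.14 (let-7), -0.19 (miR-30) and -0.39 (miR-15, miR-16 and miR-195), so part of these drops was shared by the other assays. They were 0.24 (miR-200), 0.31 (miR-17 cluster), 0.17 (miR-34), 0.12 (miR-23/27/24) and 0.30 (reference microRNAs). Relative to the other assays the angiogenesis and hypoxia list had a positive median (0.13) and a camera direction below them.

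Fewer assays gave a Ct in diabetic epidermis, 462 ± 19.9 in DFS and 505 ± 17.6 in NFS (SD, n = 3 each), a difference of -43 in which every DFS sample lay below every NFS sample (exact permutation p = 0.1, the smallest possible, 2-sided). Below Ct 40 the difference was -50.7 and at Ct 37 or less -36. With any Ct, 5 microRNAs were detected in all NFS and no DFS samples: miR-551b-3p (Ct 35.3 ± 1.52, SD, n = 3), miR-508-5p, miR-589-5p, miR-338-5p and miR-1914-3p, the last at Ct 40 throughout. miR-338-5p, the partner arm of miR-338-3p, had a Ct of 38.7 ± 1.19 in NFS (SD, n = 3). miR-524-5p was the 1 microRNA detected in all DFS and no NFS samples, at Ct 40 throughout, and Fisher's exact test of 3 samples against 0 gives p = 0.1. With a Ct of 40 as not detected, a limit chosen after seeing the data, 11 were detected in all NFS and no DFS samples and 0 the other way. Of the 5 above only miR-551b-3p stayed, and the rest were miR-431-5p, miR-124-3p, miR-675-3p, miR-410, miR-505-5p, miR-504, miR-576-5p, miR-628-3p, miR-506-3p and miR-345-5p.

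**Figure D3:**
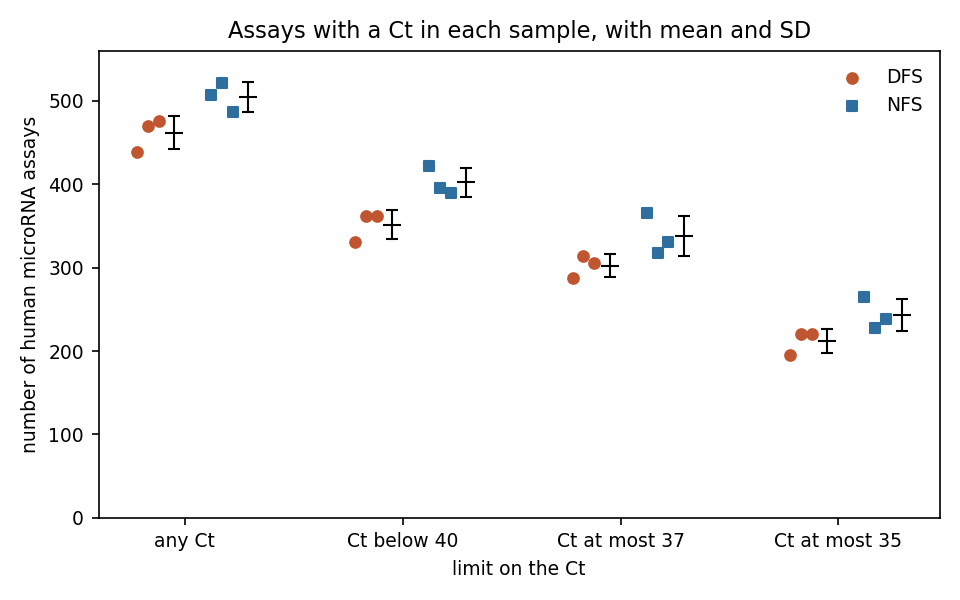
Number of human microRNA assays with a Ct (vertical axis) under 4 limits on the Ct (horizontal axis) in the 3 DFS samples (circles) and 3 NFS samples (squares), each group with its mean and SD. With any Ct the DFS samples lie between 439 and 476 and the NFS samples between 486 and 521.

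The small RNAs that serve as references also came later in DFS. SNORD49A had a Ct of 24.3 ± 0.467 in DFS and 23.8 ± 0.426 in NFS (SD, n = 3 each, exact permutation p = 0.2). Relative to it SNORD38B was at 0.14 ± 0.19 in DFS and 0.55 ± 0.07 in NFS (SD, n = 3 each, exact permutation p = 0.1), and U6 at -3.30 ± 0.46 and -1.95 ± 1.44 (SD, n = 3 each, exact permutation p = 0.3). The added spike-in UniSp6 came at Ct 23.8 ± 0.00577 in DFS and 23.6 ± 0.234 in NFS (SD, n = 3 each, exact permutation p = 0.1), and neither blank well gave a Ct.

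In the authors' deposited table of the same comparison, 6 of 200 assays had an unadjusted p under 0.05. They were the control SNORD38B (p = 0.0256), miR-31-5p (p = 0.0431), miR-338-3p (p = 0.0444), miR-136-5p (p = 0.0454), miR-31-3p (p = 0.0479) and miR-10b-5p (p = 0.0496) in the authors' deposited table. After the authors' adjustments the lowest p in their deposited table was 0.873 (Benjamini-Hochberg) or 0.496 (Westfall and Young). Among the assays with a positive difference that table also ranked miR-1248, miR-1260a and miR-940 near the top, whose log2 differences were 0.98, 0.79 and 0.60 here (limma adjusted p from 0.838 to 0.935).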

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

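Of the tests below, those on the weight of a single sample and on replaced late values for miR-31, those on assays outside the normalized table and that over the whole panel were chosen after the results were seen. A signal was present in data outside the comparison: 39 human assays that the authors' normalized table leaves out had a Ct of at most 37 in all 6 samples, 3 of them at most 35, while no blank well gave a Ct. In limma 0 of the 39 passed after adjustment and 3 had an unadjusted p under 0.05 (1 in the ordinary model). These were miR-135b-5p at a log2 difference of 2.48 (adjusted p = 0.289), miR-187-3p at 1.71 (adjusted p = 0.500) and miR-218-5p at -1.87 (adjusted p = 0.30), all named after their values were seen. Over the whole panel with at least 2 samples of each group 8 assays passed, among them miR-135b-5p (adjusted p = 0.0455), so its call depends on which assays are tested together. With at least 1 sample of each group only miR-31-5p and miR-31-3p passed (miR-135b-5p at adjusted p = 0.320), and with the global mean 0 did (lowest adjusted p = 0.446). Of the 8, the others higher in DFS were miR-31-5p, miR-31-3p and miR-877-5p, and those lower were miR-338-3p, miR-34c-5p, miR-376a-3p and miR-411-5p.

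The rise of miR-31-5p and miR-31-3p was weighed against a larger share of keratinocytes in the DFS captures, a single sample and replaced late values. The other 14 keratinocyte microRNAs had a median difference of -0.068 (interquartile range 0.54), or 0.263 relative to the other assays. The largest rise among them was 1.10 (miR-182-5p), and 8 were lower. These values lie far below the rise of miR-31-5p, which argues against a larger keratinocyte share as the source of its full size. The smallest difference of miR-31-5p with 1 sample left out was 3.13 (without DFS A, SE 1.44 from its own spread), and with replaced values missing that of miR-31-3p was 2.93 (SE 1.24 from its own spread). Neither exceeded the midpoint of the full difference by more than this SE, so a share of the rise from a single sample, and for miR-31-3p from replaced values, stays open. A difference between diabetic and non-diabetic skin also stays open, untested apart from these. Of the 10 splits of the 6 samples into 3 and 3, the real one gave 3 assays past the threshold and the highest other 2 (1 split gave as many as the real one, itself), and 10 splits are too few for a share under 0.05.

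The lower fibroblast and mesenchymal markers were weighed against less dermis in the DFS captures and a loss of weak signals. Against 15 assays of the nearest mean level, the list's members were lower by a median of -0.557 (SE 0.139 over members, which are correlated). This SE does not measure the spread between samples, so a loss of weak signals stays open. The endothelial and blood cell markers, which would come with dermis, had a median of -0.21 relative to the other assays (interquartile range 0.485), which leaves less dermis open, as it does a difference within the epidermis. Among the 10 splits 3 gave as many lists as the real 2, the highest other gave 3, and the splits are too few for a share under 0.05.

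The lower number of assays with a Ct in DFS was weighed against less amplifiable RNA. With any Ct the difference was -43, and at Ct 37 or less it was -36 (302 ± 13.7 in DFS and 338 ± 24.3 in NFS, SD, n = 3 each, exact permutation p = 0.1). Counted within 13 cycles of each sample's SNORD49A Ct, which lies near Ct 37, it was -13.67 (311 ± 23.2 in DFS and 325 ± 21.7 in NFS, SD, n = 3 each, exact permutation p = 0.5), which is consistent with less amplifiable RNA in the DFS reactions. A biological difference in the number of microRNAs was not tested apart from this.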

How the results depend on the processing

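The settings with replaced values missing, with the whole panel at 2 or more samples of each group and with a Ct of 40 as not detected were chosen after seeing the data. Over the alternatives that gave a value, miR-31-5p kept its direction in 24 of 24 (3.13 to 4.81) and was called in 17, miR-31-3p in 23 of 23 (2.93 to 5.02) and called in 16, and miR-338-3p in 22 of 22 (-3.03 to -1.83) and called in 6, with adjusted p from 1.11e-12 to 0.866, 2.48e-11 to 0.866 and 9.11e-06 to 0.980. The groups lay apart for all of them, so leaving out 1 sample could not change a sign. Many other settings left the difference of miR-31-5p at 3.77. The kept directions are therefore no separate support. The 3 assays became 0 after global mean, global median or quantile normalization, without normalization, with missing values set to 1 cycle above the highest Ct, in the ordinary model, and over the whole panel with the global mean. They became 1 among assays measured in all 6 samples (where miR-31-3p and miR-338-3p were not tested), 2 over the whole panel with at least 1 sample of each group and 8 with at least 2, and 20 with sample quality weights, whose estimation did not converge. Leaving out 1 sample gave 2 to 11. The number of lists, 2, became 1 after global mean or global median normalization or without normalization, 0 with an estimated correlation or fry, and 0 to 2 with 1 sample left out (0 without DFS A or NFS A). It was 3 with replaced values missing, where the miR-29 family was added (adjusted p = 0.0492). After quantile normalization it was 2, but the miR-17 cluster (upward, adjusted p = 0.03) took the place of the keratinocyte list (adjusted p = 0.243). With an estimated correlation, both became 0, an alternative also chosen after seeing the data. The median difference of all assays, -0.32, was -0.82 without normalization, 0.28 against the mean of the reference small RNAs and -0.63 to 0.00032 with 1 sample left out. The difference in assays with a Ct stayed between -52.3 and -31.7 with 1 sample left out and was -50.7, -36 and -32 at the other limits. The ordinary model uses each assay's own SD and few residual degrees of freedom, and which of these ended the calls was not separated. In the other settings without a call, limma's prior had 1.17 to 11.3 degrees of freedom, so the assays did not share 1 SD. The difference of miR-31-5p was 3.27 to 4.14 there, beside 3.77 in the main setting. What made the prior finite was not tested. Late Cts limit the weaker assays.

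The replicate block, with the number in the labels as a block, gave 3 assays and left 2 lists. The deviations of same-numbered samples had correlations of -0.12, 0.0594 and 0.258. DFS 2 and DFS 3 correlated best with the NFS sample of their own number, and DFS 1 with NFS 2. So few samples cannot tell whether the numbers pair them.

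The values that changed sign were these, none of them past the threshold for a single microRNA. The global mean, the global median, the mean of the reference small RNAs and no normalization differ from the main setting by 1 value per sample. Apart from replaced values, each moved all differences by a common amount, so that values near 0 crossed it. With the global mean miR-31-5p moved from 3.77 to 4.06 and miR-126-3p from -0.19 to 0.089. For quantile normalization and sample quality weights the cause was not tested. With the global mean, miR-126-3p was 0.089 and the list medians were 0.27 (keratinocyte), 0.21 (miR-200 family), 0.042 (wound healing), 0.089 (angiogenesis and hypoxia), 0.26 (miR-17 cluster), 0.13 (miR-34 family), 0.072 (miR-23/27/24) and 0.25 (reference microRNAs). With the global median, miR-126-3p was 0.037 and the same lists, without wound healing, 0.22, 0.16, 0.037, 0.20, 0.077, 0.02 and 0.20. With quantile normalization miR-126-3p was 0.16 and the medians 0.15 (keratinocyte), 0.16 (miR-200 family), 0.022 (wound healing), 0.21 (miR-17 cluster), 0.083 (miR-34 family), 0.036 (miR-23/27/24) and 0.19 (reference microRNAs), and the angiogenesis list relative to the other assays was -0.0025. Without normalization miR-205-5p was -0.20, miR-210 -0.29, miR-200c-3p -0.23 and miR-132-3p -0.31. Against the mean of the reference small RNAs miR-146a-5p was 0.077, miR-155-5p 0.27 and miR-126-3p 0.39, and the medians were 0.57 (keratinocyte), 0.52 (miR-200 family), 0.35 (wound healing), 0.11 (inflammation), 0.39 (angiogenesis and hypoxia), 0.057 (blood cell), 0.13 (let-7), 0.56 (miR-17 cluster), 0.083 (miR-30 family), 0.43 (miR-34 family), 0.38 (miR-23/27/24) and 0.56 (reference microRNAs). miR-155-5p was 0.23 with sample quality weights, and miR-126-3p 0.026 over the whole panel with the global mean.

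With 1 sample left out, the ranges that crossed 0 were -0.20 to 0.53 (miR-210), -0.48 to 0.033 (miR-126-3p) and -0.15 to 0.55 (miR-132-3p). For list medians they were -0.20 to 0.30 (keratinocyte), -0.36 to 0.23 (miR-200 family), -0.63 to 0.27 (wound healing), -0.23 to 0.35 (miR-17 cluster), -0.40 to 0.08 (miR-34 family), -0.56 to 0.23 (miR-23/27/24) and -0.34 to 0.27 (reference microRNAs). Relative to the other assays they were -0.49 to 0.02 (miR-30 family), -0.22 to 0.56 (miR-34 family), -0.56 to 0.039 (miR-15 and miR-16 family), -0.04 to 0.19 (angiogenesis and hypoxia) and -0.068 to 0.28 (wound healing).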

Other observations

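The test of the chromosomal cluster below, the checks of its stability and the count over the whole panel were chosen after the microRNA differences were seen. The microRNAs encoded between DLK1 and DIO3, an imprinted cluster expressed in stem cells, brain and mesenchyme, were lower in DFS in all 8 members that the authors' normalized table holds, with its replaced late Cts. With the replaced values missing 6 of the 8 were lower and the median of all 8 was -0.71, and with measured Cts below 40 alone miR-154-5p was higher (0.202). With the replaced values kept, the differences ran from -0.47 for miR-127-3p to -1.68 for miR-136-3p, with miR-409-3p at -1.67, miR-136-5p at -1.50, miR-495-3p at -1.48, miR-1247-5p at -1.39, miR-376c-3p at -1.23 and miR-154-5p at -0.59. The list's median was -1.43, or -1.13 relative to the other assays. None of these passed on its own in the main setting, and 5 did with sample quality weights, whose estimation did not converge. The mesenchymal list holds miR-409-3p and miR-127-3p, and the other 6 members had the same median. For comparison, 144 of all 196 assays of the normalized table were lower, and the median over the 322 assays of the whole panel fit was -0.217. Of the 67 cluster assays on the panel, 26 had a Ct below 40 in at least 2 samples of each group, and 23 of these were lower in DFS (median -0.84). Outside the normalized table these were 16 of 18 (median -0.755), among them miR-382-5p (-0.75) and, past the threshold in the fit over the whole panel, miR-376a-3p (-2.58, limma adjusted p = 0.0371) and miR-411-5p (-2.39, limma adjusted p = 0.0455). Both calls were lost with at least 1 sample of each group (limma adjusted p = 0.157 and 0.320) and with the global mean (adjusted p = 0.446 each).

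The hypothesis that the cluster is lower as a set had a camera p of 0.0469 with an estimated correlation, unadjusted. That it should also hold in every alternative was required only after this p was seen, and it did not. Without DFS A the p was 0.0844, without DFS B 0.231, without DFS C 0.0684 and without NFS A 0.0761, while it was 0.0463 without NFS B and 0.04 without NFS C. The cluster's median difference in these fits ran from -1.82 (without NFS B) to -1.03 (without DFS A). The p was 0.143 with levels recomputed from the raw Ct (median -1.09) and 0.104 after global mean normalization (median -0.80), both over 7 members. In 5 members 1 DFS value each was a replaced late Ct; with these missing the p over the 3 members measured in all samples was 0.217. The cluster may be lower in diabetic epidermis, but 6 samples and 5 replaced values leave this open.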
